A study of Xenopus tropicalis with 13 samples.

How the data were processed

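Small-intestinal epithelium of Xenopus tropicalis at NF stages 56, 61 and 66 was profiled by single-cell RNA sequencing in 13 libraries, with 10x Chromium 3' v3 chemistry. Per the labels, each biological replicate was a pool of 4 to 5 intestines, treated with Dispase (8 minutes) and EDTA (10 mM, 30 minutes on ice) and filtered at 70 µm. The labels assign the libraries to 7 biological replicates, 2 at stage 56, 2 at stage 61 and 3 at stage 66.

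The deposited matrices hold raw UMI counts per gene and barcode, 1 matrix per library, without normalization. Per the file headers they were made with Cell Ranger 7.0.0 or 7.0.1 at stages 56 and 61 and with 7.1.0 or 9.0.0 at stage 66, while the submitters' processing notes name Cell Ranger 7.0.0. Genome build, annotation release and the setting for intronic reads are not given in the sources used here. The version and stage 66 cannot be told apart; within stage 66 replicates 2 and 3, libraries made with different versions had a Pearson r of 0.998 across genes on the log scale, and genes are not independent replicates. The files list 24565 genes, of which 16707 carry a symbol, and 59920 barcodes with 762122450 UMIs. Libraries of 1 replicate were no copies of each other, with a chi-square per degree of freedom of 3.68 to 21.5 between them.

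Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 25% UMIs of the 13 mitochondrial genes, which 47142 passed; 5270 had too few genes and 10818 too high a mitochondrial share. Scrublet scores per library, from scanpy 1.11.5, marked doublets, removed at 0.8% per 1000 barcodes (1535 barcodes, 3.26%), leaving 45607 cells. Counts were log-normalised and clustered into 41 clusters without integration across libraries. Clustering took 2000 variable genes, of which 1995 were used, 50 principal components, 15 neighbours, a graph of shared neighbours and Leiden resolution 1 (leidenalg 0.10.2). A cluster was named for a class when at least 3 of its markers were at least 4 times as high as in other clusters (2 times for enterocytes), were seen in at least 5% of cells and reached a score of 1.5 (0.8 for enterocytes), with at least 50 cells. These naming thresholds were set after the clusters were seen, whereas the marker lists were fixed earlier. Cluster names mean likeness to a class; 1 BEST4-like cluster also had the macrophage marker cybb among its top 10 genes.

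UMI counts were summed per biological replicate over epithelial clusters, over all kept cells and over enterocyte-like clusters, since cells are not replicates. Epithelial clusters were all those not named for a non-epithelial class, so that clusters named for no class count among them. Epithelial sums ran from 27877144 to 154376649 UMIs. edgeR 4.0.16 (R 4.3.3) tested genes past filterByExpr by its quasi-likelihood test with TMM scaling, 1 fit over the 3 stages, and Benjamini-Hochberg adjusted p under 0.05; 15584 genes were tested in epithelial cells, at a biological coefficient of variation of 0.336. CPM in the text are TMM-scaled. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Cell numbers per class were tested with edgeR on total cells per replicate, and by exact two-sided permutation of the F statistic over the 210 assignments of replicates to stages, whose smallest p is 0.00952. The same permutation tested shares of cells with a UMI after thinning each cell to 1000 UMIs; cells below that depth (2908 of 12596, 1556 of 11852 and 4963 of 17123 epithelial cells) were left out. Limits for counts of 0 are 3 counts of the total and cover counting error alone.

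Tests, gene lists, markers, cell filters, the rule for named genes and the settings below were fixed before the data were examined, except where a later choice is stated. The rule names the 10 genes with the highest and the 10 with the lowest change per epithelial contrast among those past the threshold, with a mean of at least 20 CPM in the higher stage, replicates that do not overlap and a symbol, besides a fixed panel and up to 4 members of each list described; other comparisons take 5 each way. Those settings were each replicate left out, DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, the 13 libraries as samples, no doublet removal, cells of at least 2000 UMIs, Leiden resolutions 0.5 and 2, and thinning to 2000 UMIs or none. Replicate numbers did not pair samples across stages. A stage left with 1 replicate is assumed to vary like the others in those fits.

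The methods were tested on simulated data with 100 changed genes of each size among 14974. At stage 61 against stage 56, 3% of 2-fold and 39% of 4-fold changes were recovered with 5 false calls, and at stage 66 against stage 61 3% and 46% with 6. Changes of 2-fold were therefore mostly below detection. For 1 gene the result is not reported here. Plots were drawn with matplotlib 3.10.9, under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.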

Results

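Transcripts of single cells were counted in small-intestinal epithelium of the frog Xenopus tropicalis at Nieuwkoop-Faber (NF) stages 56, 61 and 66, which are a tadpole stage, the climax of metamorphosis and its end. The 13 libraries (10x Chromium 3' chemistry) came from 7 biological replicates, 2 at stage 56, 2 at stage 61 and 3 at stage 66, each a pool of 4 to 5 intestines per the labels. Library totals ran from 14483510 to 110139096 UMIs. Summed per replicate, the totals were 158858661 and 185185750 UMIs at stage 56, 102872798 and 37323347 at stage 61, and 62356231, 113750495 and 101775168 at stage 66. After filtering, 45607 cells remained, of which 41571 lay in epithelial clusters. These are all clusters not named for a non-epithelial class. Of their cells, 2570 of 12596, 8040 of 11852 and 6601 of 17123 at stages 56, 61 and 66 met the marker criteria of no class. The median kept cell held 14572 UMIs at stage 56, 3344 at stage 61 and 3407 at stage 66, and its mitochondrial share was 5.34%, 7.79% and 5.88%. Per the file headers, all stage 66 libraries were counted with a later Cell Ranger version than those of the other stages, so version and stage 66 cannot be told apart.

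The first question was which cell classes made up the epithelium at each stage. Cells of a class resembling BEST4 enterocytes, an ion-transporting absorptive type, made up 3.16% ± 0.25 (SD, n = 2) of kept cells at stage 56, 1.75% ± 0.346 (n = 2) at stage 61 and 9.13% ± 1.40 (n = 3) at stage 66. The rise from stage 61 was 2.38 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 0.00849). The BEST4-like cells of stage 66 lay in clusters of their own. Of these 1683 cells, 893 lay in a cluster with fabp2 at 29167.02 CPM, against 5564.26 and 2245.44 CPM in the other BEST4-like clusters. Their other cluster made up 3.55% to 4.54% of cells per stage 66 replicate. The BEST4-like cluster of stages 56 and 61 made up 2.987% and 3.255% at stage 56, and 1.493% and 1.726% at stage 61. A progenitor-like cluster, led by fgfr2, stmn1, prmt1, lgr5 and myc, rose from 0.301% ± 0.176 (35 cells) at stage 56 to 2.90% ± 0.418 (408 cells) at stage 61 and fell to 0.456% ± 0.221 (91 cells) at stage 66. Its log2 changes were 3.28 ± 0.67 and −2.66 ± 0.56 (edgeR, each adjusted p = 0.0191). Granulocyte- or mast-like cells fell from 0.704% ± 0.0191 at stage 61 to 0.0768% ± 0.0161 at stage 66 (log2 −3.18 ± 0.37, edgeR adjusted p = 0.00391). The progenitor-like rise lost its call without stage 56 replicate 2 (2.76) or stage 66 replicate 1 (3.28), and its fall without stage 66 replicate 1 (−2.57) or 2 (−2.39). With cells of at least 2000 UMIs, an alternative chosen after seeing the data, the BEST4-like rise missed the threshold (2.06).

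Tuft-like cells, the chemosensory type, numbered 0 at stage 56, 5 at stage 61 and 289 at stage 66, where they made up 1.47% ± 0.483 (edgeR adjusted p = 0.0191 against stage 56). The 0 of 13204 cells at stage 56 allows a share of up to 0.0227%, by counting error alone. That limit is for membership of the tuft-like cluster, of whose 294 cells 289 came from stage 66. Tuft-like cells of stage 56 that lay in another cluster would not be counted. Enteroendocrine-like cells, which secrete hormones, rose from 0.852% at stage 56 to 2.50% ± 0.829 at stage 66 (edgeR adjusted p = 0.0284). Macrophage- or dendritic-like cells rose from 2.38% ± 0.381 at stage 56 to 8.54% ± 3.10 at stage 61 (edgeR adjusted p = 0.0191). Enterocyte-like cells made up 65.7% ± 10.5, 13.2% ± 17.8 and 39.0% ± 31.3 of cells at the 3 stages, with no call (edgeR adjusted p = 0.392 from stage 56 to 61). Goblet-like cells, the mucus-secreting type, made up 8.42% ± 1.58 at stage 56 and 7.70% ± 4.57 at stage 66, with no call. Fibroblast-like cells made up 0.115%, 1.41% ± 1.47 and 0.196%, also with no call (log2 3.52 ± 1.25 and −2.82 ± 1.04, edgeR adjusted p = 0.0805 and 0.0857). A further 17.1%, 56.7% and 31.6% of cells met the marker criteria of no class. In all, 11 of 33 pairs of class and contrast passed in edgeR. By exact permutation over the 3 stages 3 of 11 classes passed, the BEST4-, macrophage- and granulocyte-like ones (each adjusted p = 0.0349). The progenitor-like class reached 0.0873 by exact permutation and the tuft-like class 0.0786. Permutations of 2 against 2 replicates cannot go below p = 0.333, nor those of 2 against 3 below 0.1. Calls ended for tuft-like cells without any 1 of the 5 replicates of stages 56 and 66 (log2 9.24 to 9.80). They ended for enteroendocrine-like cells without stage 56 replicate 1 (1.62) or 2 (1.48) or stage 66 replicate 1 (1.56). For macrophage-like cells they ended without stage 56 replicate 1 (1.69) or 2 (2.02), stage 61 replicate 2 (1.42), or stage 66 replicate 1 or 2 (1.84 each). The fall of enterocyte-like cells passed without stage 61 replicate 1 (−6.77), and at Leiden resolution 0.5 both their fall (−7.84) and their later rise (7.09). Both changes of fibroblast-like cells passed without stage 61 replicate 1 (4.30 and −3.61), with the replicate block (3.45 and −3.02) and with the 13 libraries as samples (3.48 and −2.67), and the rise also with cells of at least 2000 UMIs (4.72).

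**Figure D1:**
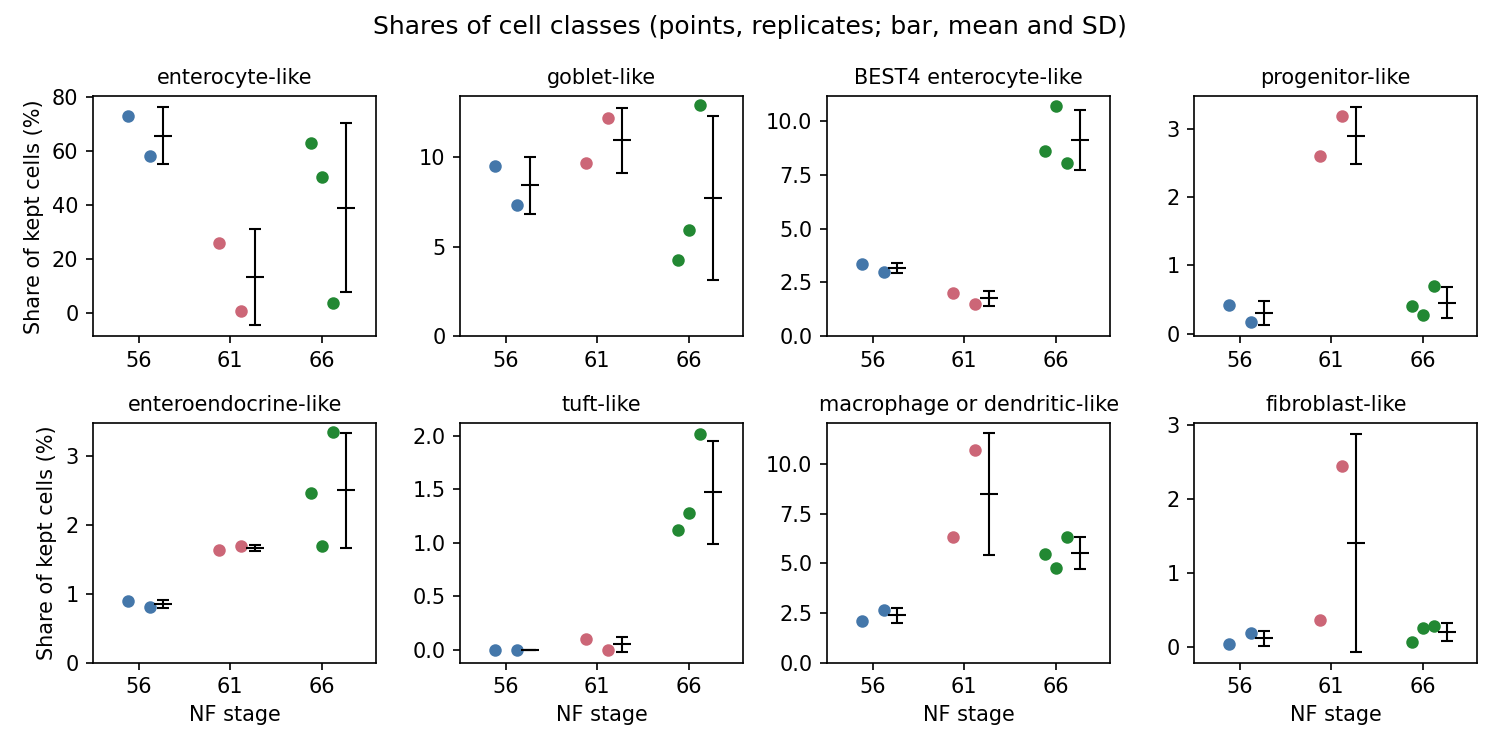
Share of kept cells (%) in 8 marker-defined classes at NF stages 56, 61 and 66, with 1 point per replicate and a bar for mean and SD. The BEST4-like share at stage 66 (9.13%) lay above all replicates of stages 56 and 61, and the progenitor-like share was 2.90% at stage 61 against 0.301% and 0.456%.

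The comparison of stage 61 with stage 56 asked what the epithelium expressed at metamorphic climax, when larval epithelium gives way to adult tissue. In epithelial cells thrb (ENSXETG00000003871), the thyroid hormone receptor gene that thyroid hormone itself induces, rose from 5.56 ± 1.42 to 497 ± 143 CPM (SD, n = 2 and 2), a log2 change of 6.48 ± 0.66 (SE, edgeR adjusted p = 0.00197). The metalloprotease gene adamts9 went from 0.237 ± 0.0376 to 134 ± 60.8 CPM (log2 9.13 ± 1.02, edgeR adjusted p = 0.00282) and bmp1 (ENSXETG00000010536), a procollagen-processing protease, from 0.0613 ± 0.0441 to 43.8 ± 22.4 CPM (edgeR adjusted p = 0.000374). The transcription factor genes zbtb20 (log2 7.02 ± 0.57), nfix (7.50 ± 0.46) and nfic (7.42 ± 0.50) rose as well, and nfix and zbtb20 were still at 126 ± 22.2 and 350 ± 110 CPM at stage 66. bhmt, for betaine-homocysteine methyltransferase, rose by 9.27 ± 0.42 (edgeR adjusted p = 5.83e-05).

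The gene cyp7a1 (ENSXETG00000005661), whose enzyme sets the rate of bile acid synthesis, fell from 55.2 ± 8.44 to 1.86 ± 0.23 CPM (log2 −4.88 ± 0.54, edgeR adjusted p = 0.00267). hmgcs1 (ENSXETG00000016587), of cholesterol synthesis, fell from 171 ± 93.5 to 7.75 ± 3.79 CPM (log2 −4.46 ± 0.87, edgeR adjusted p = 0.0155), a call that ended without stage 56 replicate 2 (−3.78) or stage 61 replicate 2 (−4.04). fabp1 (ENSXETG00000001938), a fatty acid binding protein of enterocytes, fell from 2810 ± 984 to 180 ± 172 CPM (edgeR adjusted p = 0.0345). It missed the threshold without stage 56 replicate 1 (−4.24) or 2 (−3.57), stage 61 replicate 2 (−3.23) or stage 66 replicate 1 (−3.97) or 2 (−3.96). dnase1l2 fell by 5.99 ± 0.42 on the log2 scale and the thermogenic uncoupling protein gene ucp1 from 93.1 ± 48.2 to 4.33 ± 0.882 CPM (edgeR adjusted p = 0.00245).

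In all, edgeR called 2416 of 15584 genes tested in epithelial cells, 1054 up and 1362 down. Without stage 61 replicate 2 it called 255, of which 252 were among the 2416. It called 1448 without stage 56 replicate 1, 493 without stage 56 replicate 2 and 1412 without stage 66 replicate 2. TMM scaling sets the level of this comparison. Without scaling factors, an alternative chosen after seeing the data, the median gene moved by 0.97 from stage 56 to 61, by −1.04 from stage 61 to 66 and by −0.07 from stage 56 to 66. The calls from stage 56 to 61 then numbered 5837 up and 540 down.

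**Figure D2:**
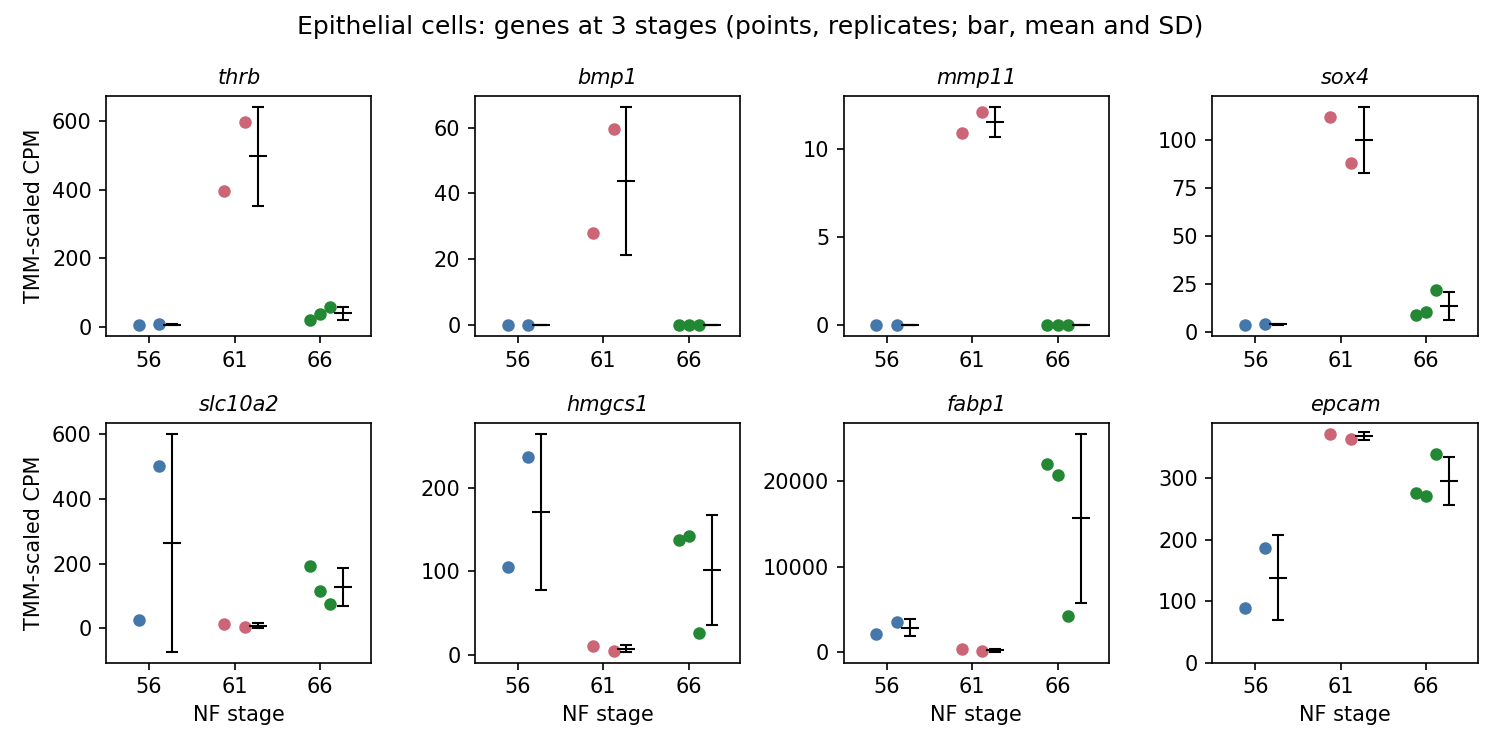
TMM-scaled CPM of 8 genes in epithelial cells at NF stages 56, 61 and 66, with 1 point per replicate and a bar for mean and SD. thrb, bmp1, mmp11 and sox4 had their highest mean at stage 61 (497, 43.8, 11.5 and 99.9 CPM), and fabp1, hmgcs1 and slc10a2 their lowest.

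Among the 38 gene lists fixed beforehand, that of thyroid hormone response and metabolism showed 15 of 33 members up and 2 down at stage 61 (16 and 3 adjusted over the list alone; camera adjusted p = 7.38e-10; adjusted p = 0.344 with an estimated correlation). Its risen members included klf9 (18.9 ± 3.06 to 92.6 ± 9.57 CPM), an immediate target of the hormone, bcl6 (1.57 ± 0.686 to 74.2 ± 10.4 CPM), mecom (3.08 ± 2.32 to 66.3 ± 5.24 CPM) and mmp11 (ENSXETG00000022372), for stromelysin-3. mmp11 stood at 0.00376 ± 0.00532 CPM at stage 56 and 11.5 ± 0.88 CPM at stage 61 (edgeR adjusted p = 0.000253). Of 30 members of TGF-beta and BMP signalling, 8 rose and 2 fell (10 and 2 adjusted over the list alone), pmepa1 by 2.66 ± 0.34 (camera adjusted p = 0.0015; adjusted p = 0.68 with an estimated correlation). In Hedgehog signalling 5 of 12 rose and 1 fell (6 and 2 adjusted over the list alone), with cdon, a co-receptor, up by 1.80 ± 0.25 (camera adjusted p = 0.00741; adjusted p = 0.68 with an estimated correlation). Wnt signalling had 6 of 38 up and 1 down (8 and 1 adjusted over the list alone; camera adjusted p = 0.024; adjusted p = 0.68 with an estimated correlation). Its ligand gene wnt5a went from 0.425 ± 0.101 to 11.2 ± 1.07 CPM (edgeR adjusted p = 0.00851), a call lost without stage 61 replicate 2 (log2 4.81). Without scaling factors 22 rose and 2 fell in thyroid hormone response, 20 and 1 in TGF-beta and BMP, 9 and 0 in Hedgehog and 23 and 1 in Wnt signalling. Of 22 matrix metalloproteinases and inhibitors 5 rose (8 up and 1 down adjusted over the list alone; camera adjusted p = 0.00102; adjusted p = 0.68 with an estimated correlation). For 21 adult intestinal stem cell genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.024; adjusted p = 0.68 with an estimated correlation). Of these, mex3a rose by 2.50 ± 0.34, while lgr5, the classical crypt stem cell marker, stood at 10.3 ± 1.19 and 11.1 ± 2.71 CPM. Enteroendocrine genes had 3 of 19 up (6 adjusted over the list alone; camera adjusted p = 0.000654; adjusted p = 0.68 with an estimated correlation). Without scaling factors 13 metalloproteinase, 14 stem cell and 16 enteroendocrine genes rose.

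In cell division 27 of 34 members fell and 0 rose at stage 61 (29 adjusted over the list alone; camera adjusted p = 6.09e-15; adjusted p = 0.68 with an estimated correlation). The mitotic kinase gene cdk1 stood at 48.3 ± 13.5 and 6.80 ± 0.879 CPM, a call lost without stage 61 replicate 2 (log2 −2.97). The proliferation genes of the fixed panel had no call. Their log2 changes were −0.92 for mki67, which was 0.04 without scaling factors, and 0.05 for top2a. Oxidative phosphorylation had 48 of 74 down (70 adjusted over the list alone; median log2 −2.12; camera adjusted p = 1.97e-21; adjusted p = 0.68 with an estimated correlation). Cytosolic ribosomal proteins had 26 of 75 down (70 adjusted over the list alone; median −1.64; camera adjusted p = 1.2e-20; adjusted p = 0.68 with an estimated correlation). Mitochondrial fatty acid oxidation had 8 of 19 down and 1 up (14 and 1 adjusted over the list alone; camera adjusted p = 1.77e-05; adjusted p = 0.68 with an estimated correlation). Without scaling factors 13 division members fell and 1 rose, 35 fell in oxidative phosphorylation, 3 among ribosomal proteins and 4, with 1 up, in fatty acid oxidation. Brush border digestion and nutrient transport had 10 of 37 down and 1 up (13 and 2 adjusted over the list alone; camera adjusted p = 0.000604; adjusted p = 0.68 with an estimated correlation). Its median of −0.83 flipped to 0.10 without scaling factors, with 6 down and 7 up. DNA replication had 6 of 40 down (6 down and 1 up adjusted over the list alone; camera adjusted p = 0.00744; adjusted p = 0.713 with an estimated correlation). Its median of −0.74 flipped to 0.27 without scaling factors, with 2 down and 3 up. Proteasome genes had 2 of 38 down and 1 up (0 each way adjusted over the list alone; camera adjusted p = 0.000903; adjusted p = 0.713 with an estimated correlation). Their median of −1.02 was −0.05 without scaling factors, with 1 down and 2 up.

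**Figure D3:**
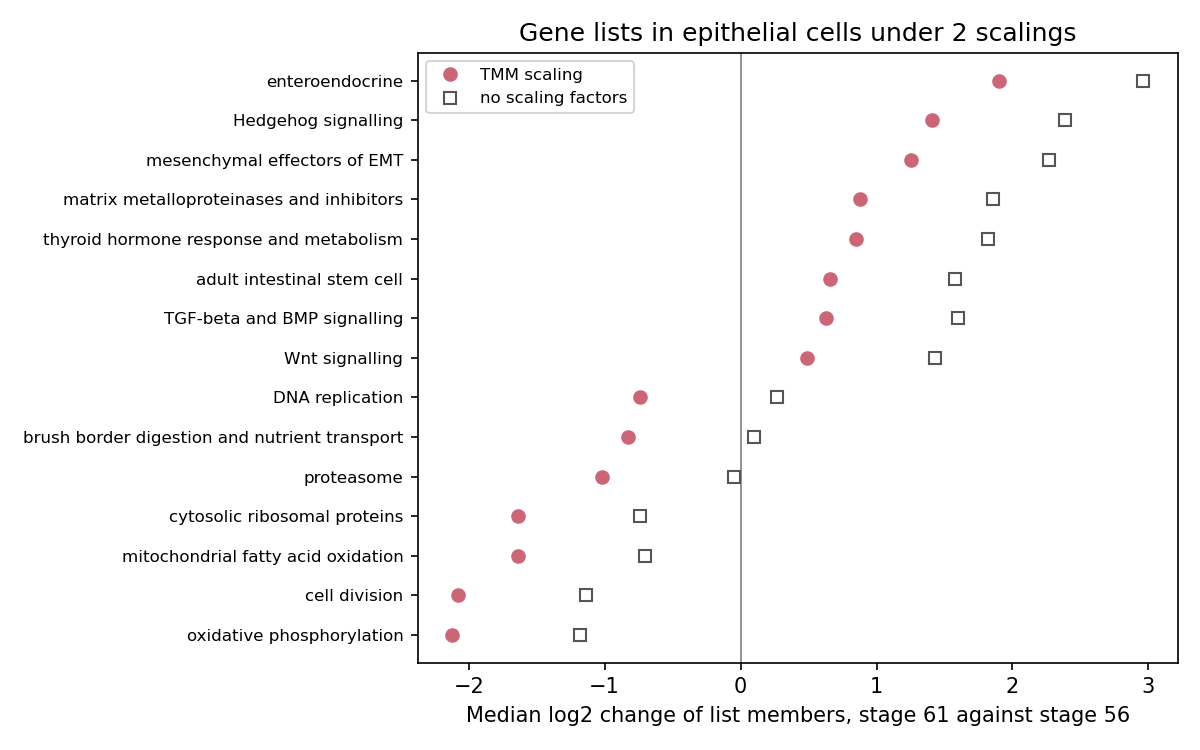
Median log2 change from stage 56 to 61 of the members of the 15 called gene lists in epithelial cells, with TMM scaling (circles) and without scaling factors (squares). Oxidative phosphorylation (−2.12 and −1.18) lay below 0 under both, and brush border digestion changed sign (−0.83 and 0.10).

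Because the series names epithelial-mesenchymal transition, the mesenchymal programme in epithelial cells was compared across stages. Of 24 mesenchymal effectors, 6 rose at stage 61 and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.000903; adjusted p = 0.68 with an estimated correlation). itgb1 (ENSXETG00000026716), an integrin subunit, went from 37.1 ± 5.20 to 150 ± 35.4 CPM, a call lost without stage 56 replicate 2 (log2 1.85). Without scaling factors 14 effectors and 6 of the EMT transcription factors rose, as did 4 of 12 fibroblast markers. The itgb1 partner itga5 went from 0.0478 ± 0.00374 to 5.29 ± 2.56 CPM (edgeR adjusted p = 0.00146). The fibronectin gene fn1 reached 1.47 ± 1.40 CPM from 0.0327 ± 0.025 (edgeR adjusted p = 0.0126) and lost its call without stage 61 replicate 2 (3.83). vim (ENSXETG00000007462), for the mesenchymal filament vimentin, stood at 0.138 ± 0.0782 and 0.148 ± 0.0637 CPM (edgeR adjusted p = 0.969), with a change of −0.41 to 0.74 when 1 replicate was left out. The other copy, vim.2 (ENSXETG00000008017), stood at 0.0418 ± 0.0473 and 0.184 ± 0.0685 CPM, with no call (log2 2.03 ± 0.90, edgeR adjusted p = 0.14) and a change of 1.20 to 4.23 when 1 replicate was left out. Of 14 EMT transcription factors 2 rose and 1 fell (3 and 1 adjusted over the list alone), and the list missed the threshold (limma camera adjusted p = 0.0592). Its main riser was sox4 (ENSXETG00000037031), from 4.09 ± 0.337 to 99.9 ± 16.8 CPM (log2 4.61 ± 0.50, edgeR adjusted p = 0.00245). In turn snai1, zeb1 and zeb2 had log2 changes of 1.84 ± 1.22, 0.82 ± 0.76 and 0.56 ± 0.77 with no call. twist1 and snai2, with 5 and 23 UMIs in total, were too scarce to test. Of 37 epithelial junction and identity genes 4 rose and 3 fell (camera adjusted p = 0.482), against 20 and 1 without scaling factors. epcam (ENSXETG00000022614) stood at 138 ± 68.8 and 368 ± 5.86 CPM (edgeR adjusted p = 0.0619) and cdh1, for E-cadherin, at 282 ± 14.1 and 490 ± 92.6 CPM (edgeR adjusted p = 0.164). Fibroblast markers in the epithelial clusters had 0 of 12 called, with a median log2 change of 0.75 (limma camera adjusted p = 0.0857).

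Per cell, with each cell thinned to 1000 UMIs, sox4 was seen in 0.448% ± 0.207 of epithelial cells at stage 56, 12.9% ± 0.675 at stage 61 and 1.87% ± 0.973 at stage 66 (exact permutation p = 0.019, n = 2, 2 and 3). The shares of sox4, mmp11 and the collagens were added after seeing the data. For sox4, already called in the same counts, this p is no independent test. In macrophage-like cells of stage 61 the share was 4.23%, at a median depth of 2572 UMIs against 3441 in epithelial cells. Whether macrophage-like cells express sox4 themselves is unknown, so that share is no clean measure of free RNA. At stage 61, 475 of them lay in a cluster that held epcam at 149.2 CPM and sox4 at 62.17 CPM. Without any 1 stage 66 replicate the exact permutation p of sox4 was 0.0667, the smallest that 2, 2 and 2 replicates can give. Any of the EMT transcription factors was seen in 11.1% ± 0.848, 29.7% ± 2.75 and 10.9% ± 3.44 of epithelial cells (exact permutation p = 0.0952). Without sox4, tcf3, tead1, yap1 and klf8, a choice made after seeing the data, these shares were 1.18% ± 0.223, 3.35% ± 0.772 and 2.38% ± 0.703 (exact permutation p = 0.0667; 0.019 thinned to 2000 UMIs and 0.0476 with doublets kept). vim was seen in 0%, 0.0321% and 0.205% (exact permutation p = 0.00952, the smallest possible). Of the 26 epithelial cells with vim at stage 66, 24 were enteroendocrine-like (6.65% of 361 cells), against 2 of 4290 enterocyte-like cells (0.0466%). Macrophage-like cells give no background for the EMT transcription factors, since their main cluster held zeb2 at 281.06 CPM, so the part of free RNA in those shares is unknown. Thinned to 2000 UMIs the p of vim was 0.21 and without any 1 replicate it lay between 0.05 and 0.0667, where 0.0667 is again the smallest possible without a stage 66 replicate. mmp11 was seen in 2.11% ± 0.0948 of epithelial cells at stage 61 against 0.962% in macrophage-like cells (exact permutation p = 0.0952). Cells with at least 2 UMIs of division genes made up 10.4%, 6.62% and 11.9% (exact permutation p = 0.124), and 16.5% of macrophage-like cells at stage 61. Fibroblast markers were seen in 31.7%, 58.8% and 27.7% of epithelial cells (exact permutation p = 0.0571), against 15.8% of macrophage-like cells at stage 61. Without stage 56 replicate 2 that p was 0.0333. The collagen genes col1a1, col1a2 and col3a1 among them were seen in 0.144%, 0.66% and 0.095%, and the other fibroblast markers were not counted apart.

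**Figure D4:**
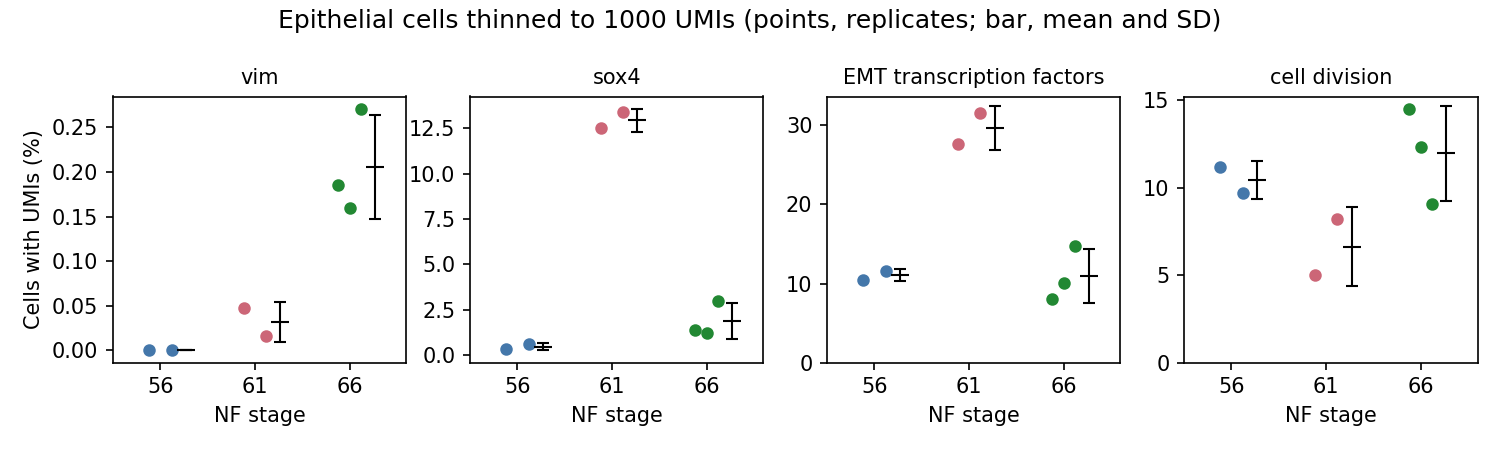
Share of epithelial cells (%) with UMIs of vim, sox4, EMT transcription factors and cell division genes after thinning each cell to 1000 UMIs, with 1 point per replicate and a bar for mean and SD. sox4 stood at 12.9% at stage 61 against 0.448% and 1.87%, and vim at or below 0.205%.

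The comparison of stage 66 with stage 61 asked how the climax epithelium differs from that of the froglet. The intestinal alkaline phosphatase gene alpi.1 (ENSXETG00000022768), a brush border enzyme, rose from 2.62 ± 1.05 to 690 ± 256 CPM (log2 8.05 ± 0.72, n = 2 and 3, edgeR adjusted p = 0.000292). The fucosyltransferase gene fut2 rose from 0.236 ± 0.0759 to 21.9 ± 3.51 CPM while another, fut9, fell from 29.8 ± 9.81 to 0.259 ± 0.101 CPM (edgeR, each adjusted p = 5.02e-05). fabp1 reached 15600 ± 9900 CPM (edgeR adjusted p = 0.00477). krt19 and krt7, keratins of simple epithelia, rose by 3.76 ± 0.48 and 3.33 ± 0.41. The lipid transporter gene abca12 fell by 6.47 ± 0.40 and the trefoil factor gene tff3.2 by 5.77 ± 0.52 (edgeR adjusted p = 5.76e-05 and 0.000297).

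Several genes that had risen at stage 61 fell again, while nfix and nfic rose further (2.64 ± 0.34 and 1.41 ± 0.34; edgeR adjusted p = 0.00135 and 0.0136). thrb changed by −3.69 ± 0.49 to 38.4 ± 18.8 CPM, klf9 by −4.15 ± 0.26 to 5.19 ± 0.784 CPM, and sox4 by −2.86 ± 0.39 to 13.7 ± 7.25 CPM (edgeR adjusted p = 0.00163, 5.93e-05 and 0.00186). mmp11 stood at 0.0083 ± 0.00719 and bmp1 at 0.00424 ± 0.00734 CPM at stage 66. vim rose from 0.148 ± 0.0637 to 0.987 ± 0.621 CPM (edgeR adjusted p = 0.0186), a call lost without stage 61 replicate 1 (2.40) or 2 (3.25) and without scaling factors (1.81). Enteroendocrine-like cells held vim at 3.92, 2.08 and 50.2 CPM of summed UMIs at the 3 stages, and no other epithelial class of stage 66 held it above 0.414 CPM. vim.2 stood at 0.0721 ± 0.0308 CPM at stage 66, with a change of −1.33 ± 0.82 (edgeR adjusted p = 0.219). The pro-apoptotic genes fas, for a death receptor, and bcl2l11, for BIM, had risen at stage 61 by 2.87 ± 0.33 and 2.77 ± 0.37 and fell by 3.12 ± 0.29 and 3.39 ± 0.32 afterwards. Their list, apoptosis, had 5 of 35 up and 1 down at stage 61 (the same numbers adjusted over the list alone), with no call (limma camera adjusted p = 0.459). Its median of −0.14 flipped to 0.77 without scaling factors, with 17 up and 0 down. At stage 66 it had 5 up and 9 down against stage 61, also with no call (limma camera adjusted p = 0.246), and 2 up and 20 down without scaling factors.

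Among the lists, oxidative phosphorylation had 69 of 74 members up (72 adjusted over the list alone) and cytosolic ribosomal proteins 66 of 75 (71), with camera adjusted p = 6.52e-18 and 1.17e-17 (each adjusted p = 0.588 with an estimated correlation). Without scaling factors 49 rose and 1 fell in the first of these, and 33 rose and 1 fell in the other. The kinase gene cdk1 rose by 2.83 ± 0.46, while top2a changed by 0.27 with no call. Cell division had 30 of 34 up (31 adjusted over the list alone) and DNA replication 25 of 40 up and 1 down (31 and 1), with camera adjusted p = 2.18e-09 and 2.92e-06 (each adjusted p = 0.588 with an estimated correlation). Without scaling factors they had 9 up and 1 down, and 4 up and 3 down. The cholesterol transporter gene npc1l1 rose by 2.85 ± 0.46. Its list, lipid absorption, had 11 of 24 up and 1 down (the same numbers adjusted over the list alone), and fatty acid oxidation 13 of 19 up (14), with camera adjusted p = 0.00189 and 0.000114 (each adjusted p = 0.588 with an estimated correlation). MHC and antigen presentation had 7 of 10 up (7 adjusted over the list alone; camera adjusted p = 0.0204) and keratins 6 of 12 up and 1 down (7 and 1; 0.0129), each adjusted p = 0.588 with an estimated correlation. Proteasome genes had 14 of 38 up (16 adjusted over the list alone; camera adjusted p = 0.000114; adjusted p = 0.625 with an estimated correlation). Without scaling factors 1 proteasome gene rose and 1 fell, and fatty acid oxidation had 7 up and 2 down, lipid absorption 9 and 3, MHC 3 and 2, and keratins 3 and 2.

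Lists that fell were led by basement membrane, with 11 of 20 down and 1 up (the same numbers adjusted over the list alone; camera adjusted p = 0.000396; adjusted p = 0.588 with an estimated correlation). Its laminin gene lama1 went from 9.42 ± 0.538 to 0.0603 ± 0.0323 CPM. Thyroid hormone response had 14 of 33 down and 5 up (15 and 6 adjusted over the list alone; camera adjusted p = 0.000495; adjusted p = 0.588 with an estimated correlation). TGF-beta and BMP signalling had 9 of 30 down and 2 up, including smad3 (−2.55 ± 0.26) and the receptor gene tgfbr2 (−2.66 ± 0.30), and Wnt signalling 11 of 38 down and 1 up, with the same numbers adjusted over the list alone (camera adjusted p = 0.0129 and 0.0345; each adjusted p = 0.588 with an estimated correlation). Mesenchymal effectors had 8 of 24 down and 1 up, also when adjusted over the list alone, and matrix metalloproteinases 10 of 22 down and 3 up (11 and 3), with camera adjusted p = 0.0203 and 0.0217 (each adjusted p = 0.588 with an estimated correlation). Stem cell genes had 7 of 21 down (5 adjusted over the list alone; camera adjusted p = 0.0343; adjusted p = 0.59 with an estimated correlation). EMT transcription factors had 4 of 14 down and 2 up, with no call (camera adjusted p = 0.147). Fibroblast markers in the same epithelial clusters had 2 of 12 down and 1 up, with no call (camera adjusted p = 0.356). Their median log2 change was −1.41, against −1.16 for the mesenchymal effectors. Without scaling factors 23 thyroid hormone, 23 TGF-beta and BMP, 26 Wnt, 14 mesenchymal effector, 16 metalloproteinase, 13 stem cell and 7 EMT transcription factor genes fell. edgeR called 5839 genes, 2949 up and 2890 down, against 1000 up and 7762 down without scaling factors. Without stage 61 replicate 2 it called 1762, without stage 66 replicate 1 3472 and without stage 66 replicate 2 3284.

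The comparison of stage 66 with stage 56 set the froglet against the tadpole epithelium. ntn1 (ENSXETG00000014390), for the guidance cue netrin-1, rose from 0.113 ± 0.0538 to 185 ± 66.5 CPM (log2 10.67 ± 0.67, n = 2 and 3, edgeR adjusted p = 6.56e-05). nfix rose from 0.109 ± 0.0476 to 126 ± 22.2 CPM and nfic by 8.83 ± 0.51 (edgeR adjusted p = 2.55e-05 and 4.55e-05). The alkaline phosphatase genes went opposite ways: alpi.1 rose by 6.07 ± 0.65 while alpi.2 (ENSXETG00000032063) fell from 1700 ± 217 to 70.3 ± 32.8 CPM (edgeR adjusted p = 0.000576 and 0.00239). The carboxypeptidase gene cpo.2 fell from 2900 ± 404 to 18.4 ± 4.43 CPM, tff3.2 from 498 ± 202 to 2.72 ± 1.13 CPM, and lama1 by 8.01 ± 0.37. klf9 was lower by 1.87 ± 0.25, and thrb higher by 2.79 ± 0.53 (edgeR adjusted p = 0.00175 and 0.0103), the latter call lost without stage 56 replicate 1 (2.62).

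Of the lists, enteroendocrine genes had 6 of 19 up and 1 down (8 and 1 adjusted over the list alone) and MHC and antigen presentation 4 of 10 up (7), with camera adjusted p = 0.00277 for each (adjusted p = 0.966 with an estimated correlation). DNA replication had 1 of 40 up (0 adjusted over the list alone; camera adjusted p = 0.0128; adjusted p = 0.966 with an estimated correlation). Of 6 urea cycle genes 2 fell (3 adjusted over the list alone; camera adjusted p = 0.0316; adjusted p = 0.966 with an estimated correlation). Among them ass1, for argininosuccinate synthase, stood at 80.0 ± 16.3 and 8.41 ± 2.11 CPM. Cell division (0 of 34 called), ribosomal proteins (0 of 75) and oxidative phosphorylation (2 up and 1 down of 74) had median log2 changes of −0.11, 0.17 and 0.10 and no list call, at limma camera adjusted p = 0.75, 0.48 and 0.48. EMT transcription factors had 3 of 14 up and 2 down (camera adjusted p = 0.895) and mesenchymal effectors 1 of 24 each way (camera adjusted p = 0.75). edgeR called 2022 genes, 935 up and 1087 down (860 and 1111 without scaling factors). Without stage 56 replicate 1 it called 1003, without stage 66 replicate 1 1327 and without stage 66 replicate 2 1272. Over the 3 contrasts in the order given, limma camera with an estimated correlation passed 0 of 38 lists each (2, 1 and 1 at an unadjusted p under 0.05), while fry, which asks whether a list moves on balance without comparing it with other genes, passed 2, 13 and 1.

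Genes with a peak or a trough at climax were counted by both contrasts. mxd1, for a MYC antagonist, stood at 7.32 ± 2.65, 159 ± 6.91 and 4.82 ± 1.26 CPM at stages 56, 61 and 66, and bcl6 at 1.57 ± 0.686, 74.2 ± 10.4 and 4.02 ± 1.49 CPM. cyp1a1, for a xenobiotic-metabolising enzyme, stood at 2.67 ± 0.0386, 82.6 ± 45.5 and 2.61 ± 0.871 CPM. Troughs were seen for cyp7a1, at 55.2 ± 8.44, 1.86 ± 0.23 and 58.6 ± 27.7 CPM, and for ucp1, at 93.1 ± 48.2, 4.33 ± 0.882 and 129 ± 19.2 CPM. In edgeR's fit 659 genes were highest at stage 61 and 1025 lowest, where independent lists of the same sizes would share 195 and 258. Both contrasts use the same stage 61 replicates. In 20 simulated draws without change, at most 0 genes were highest and 1 lowest. These draws varied each gene on its own, without the shifts that many genes share between replicates. Enterocyte-like cells, for instance, made up 25.7% and 0.6% of the stage 61 replicates. The draws therefore cannot exclude such shared variation as a source of the counts. The highest numbered 105 without stage 61 replicate 2, 151 without stage 56 replicate 2, 399 without stage 56 replicate 1, 415 without stage 66 replicate 1 and 344 without stage 66 replicate 2. The lowest numbered 43, 154, 1555, 593 and 469 without stage 61 replicate 2, stage 56 replicate 2, stage 61 replicate 1, stage 66 replicate 1 and stage 66 replicate 2. Without scaling factors they numbered 4654 and 325.

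The same contrasts were run on all kept cells and within enterocyte-like cells. The enterocyte-like cells of each stage lay in clusters of their own, such as 1 with 1363 cells at stage 61 and 0 at the other stages, so that different clusters are compared. Within enterocyte-like cells thrb rose from 3.10 to 471 CPM at stage 61 (log2 7.24 ± 0.62, edgeR adjusted p = 5.28e-05) and zbtb20 by 6.96 ± 0.61. There cyp7a1 fell by 6.21 ± 0.91 and dnase1l2 by 5.81 ± 0.55 (edgeR adjusted p = 0.0041 and 7.86e-05). From stage 61 to 66 alpi.1 rose by 8.06 ± 0.87 and fut9 fell by 8.07 ± 0.52. From stage 56 to 66 nfix rose by 10.44 ± 0.59 and cpo.2 fell by 7.72 ± 0.56 (edgeR adjusted p = 3.09e-07 and 1.67e-06). edgeR called 1422 genes (502 up, 920 down) from stage 56 to 61, 4715 (2508 up, 2207 down) from 61 to 66 and 2173 (968 up, 1205 down) from 56 to 66. Stage 61 replicate 2 held 51 such cells, and without stage 61 replicate 1 the first count was 50 and the second 664. Of the 1422 calls 47 were then kept and 37 had a change of opposite sign. The first count was also 2135 without stage 56 replicate 1, 459 without stage 56 replicate 2 and 425 without stage 61 replicate 2. In all cells bhmt rose by 9.12 ± 0.42 and cyp7a1 fell by 5.04 ± 0.54 at stage 61. The calls numbered 2642 (1241 up, 1401 down), 5532 (2728 up, 2804 down) and 1804 (828 up, 976 down) for the contrasts in the same order. The first fell to 188 without stage 61 replicate 2, 227 without stage 56 replicate 2, 544 without stage 56 replicate 1, 1573 without stage 66 replicate 1 and 1330 without stage 66 replicate 2. The second fell to 1336 without stage 61 replicate 2, 2646 without stage 66 replicate 1 and 2464 without stage 66 replicate 2, and the third to 688 without stage 56 replicate 1, 1061 without stage 56 replicate 2, 1060 without stage 66 replicate 1 and 1058 without stage 66 replicate 2.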

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

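The counts without scaling factors, without low-UMI clusters and, for class shares, with cells of at least 2000 UMIs were chosen only after the results were seen. So were the thinned shares of sox4, mmp11, the collagens and the reduced list of EMT transcription factors. Of 9932 values of named genes under the alternatives 49 had the opposite sign, over 32 pairs of gene and contrast and 0 of them called, such as vim (−0.41 to 0.74), lgr5 (−0.16 to 0.30) and zeb2 (−0.14 to 2.16) from stage 56 to 61. Within enterocyte-like cells 37 of the 1422 genes called from stage 56 to 61 and 321 of the 4715 called from 61 to 66 changed sign without stage 61 replicate 1. With a replicate left out, counts of called genes in epithelial cells ran from 255 to 3105 from stage 56 to 61, from 1762 to 5922 from stage 61 to 66 and from 1003 to 1957 from stage 56 to 66. In all cells they ran from 188 to 3888, 1336 to 5841 and 688 to 1932, and in enterocyte-like cells from 50 to 2135, 664 to 5426 and 1474 to 2802. Genes highest at stage 61 ran from 105 to 741 and lowest from 43 to 1555, called lists from 15 to 20, 13 to 18 and 2 to 8, and class pairs from 2 to 14. Exact permutation p ran from 0.05 to 0.0667 for vim, 0.0667 to 0.2 for EMT transcription factors, 0.0333 to 0.2 for fibroblast markers and 0.0667 to 0.45 for dividing cells. Fewer replicates give permutations a higher smallest p, while the cause of the other moves was not tested. With DESeq2, 4119 epithelial genes passed from stage 56 to 61, 4542 and 2874 in all cells from stage 56 to 61 and from 56 to 66, and 1009 were highest and 1756 lowest at stage 61; the cause was not tested. With the 13 libraries as samples, which counts 1 pool more than once, 7966, 9299 and 5552 epithelial genes passed, 8349, 9347 and 5577 in all cells, and 2670 and 2935 were highest and lowest at stage 61. Without scaling factors 6377 and 8762 passed from stage 56 to 61 and from 61 to 66, and 4654 and 325 were highest and lowest, since the median gene then moved by 0.97 and −1.04; the medians of brush border and DNA replication genes from stage 56 to 61 then flipped to 0.10 and 0.27. With an estimated correlation 0, 0 and 0 lists passed; fry passed 2 from stage 56 to 61 and 1 from 56 to 66, and the replicate block gave 9 lists for the last; the cause was not tested. Of 33 class pairs, 5 passed with cells of at least 2000 UMIs, and 3 classes passed by exact permutation over the 3 stages. The vim share had p = 0.21 at 2000 UMIs and 0.152 unthinned by exact permutation; the cause was not tested. For single named genes, 8932 values kept their side of the threshold, 348 passed it and 652 missed it under the alternatives, and for shares 410, 21 and 48. Without low-UMI clusters 2401 of the 2416 epithelial calls from stage 56 to 61 were kept. Of the 667479762 UMIs of all epithelial cells, twist1 had 5 and snai2 23, and whether depth or lack of expression sets these counts was not tested.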

Other observations

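The comparisons within goblet-like and progenitor-like cells and 7 of the 9 tests of explanations were chosen only after the results they concern were seen; those of goblet-like pairs and of doublet scores were written before. Goblet-like cells, 1 secretory class with cells in every replicate, were compared between the stages as well. From stage 56 to 61 thrb rose in them from 7.37 to 555 CPM (log2 6.23 ± 0.52, edgeR adjusted p = 3.32e-05), nfix by 8.00 ± 0.63, mecom by 4.62 ± 0.36, klf9 by 2.69 ± 0.36, itgb1 by 2.15 ± 0.34 and sox4 from 14.2 to 84.4 CPM (edgeR adjusted p = 0.0023). A goblet-like cluster that also expressed enterocyte genes held 44.9% and 6.76% of the goblet-like cells of the stage 56 replicates and at most 1.79% of those of stage 61. Without it thrb rose by 5.62 ± 0.53, nfix by 6.83 ± 0.69, mecom by 5.65 ± 0.45, klf9 by 2.96 ± 0.42, itgb1 by 1.94 ± 0.35 and sox4 by 1.90 ± 0.35, against 2.59 ± 0.40 with it. Goblet-like cells of stage 66 lay in a cluster of their own (1564 cells, against 0 at stage 56 and 8 at stage 61), so that contrasts with stage 66 compare different clusters. Of 28 thyroid hormone genes tested there 11 rose and 1 fell (14 and 0 without that cluster), of 34 division genes 12 fell (3 of 27), and of 74 ribosomal protein genes 1 fell (2), at a median log2 change of −1.21 (−1.18) against −1.64 in all epithelial cells. Of 9 goblet secretory genes 0 were called (5 fell without that cluster), at a median log2 change of −1.19 (−1.82). fn1 stood at 0.188 and 2.26 CPM with no call (edgeR adjusted p = 0.0658). edgeR called 1436, 2688 and 1103 of 11453 genes in goblet-like cells over the contrasts from stage 56 to 61, 61 to 66 and 56 to 66, and 1859, 2926 and 1692 without that cluster. A shared cluster held 826 goblet-like cells of stage 56 and 1528 of stage 61. At Leiden resolution 2 the stages parted more, with 612 and 112 cells in a goblet-like cluster and 213 and 1418 in another. The contrast from stage 56 to 61 may thus also compare different kinds of goblet-like cells.

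Progenitor-like cells were set against the other epithelial cells of the same replicate, over 7 replicates. The cluster was formed on the same counts, so the differences describe it and are no independent test. They had higher dll1, for a Notch ligand of secretory progenitors (log2 4.25 ± 0.36, higher in 7 of 7 replicates) and higher sox4 (143 against 52.4 CPM, edgeR adjusted p = 0.0228, 6 of 7). Of 36 brush border genes 35 were lower (camera adjusted p = 4.31e-27; adjusted p = 0.0245 with an estimated correlation), as were 21 of 23 lipid absorption genes (camera adjusted p = 7.33e-18; adjusted p = 0.0245 with an estimated correlation) and 9 of 11 enteroendocrine genes (camera adjusted p = 1.43e-05; adjusted p = 0.357 with an estimated correlation). Cell division had 32 of 34 genes higher (median log2 2.52, camera adjusted p = 3.55e-24). DNA replication had 36 of 40 higher and 2 lower (camera adjusted p = 3.08e-24). Both had adjusted p = 0.337 in camera with an estimated correlation. Of 18 adult intestinal stem cell genes 7 were higher and 2 lower, and the list missed the threshold (camera adjusted p = 0.0526). Of 9 EMT transcription factors tested 3 were higher and 1 lower (limma camera adjusted p = 0.0967), and 0 of 9 mesenchymal effectors differed in edgeR (limma camera adjusted p = 0.989). epcam was higher by 0.87 ± 0.29 (edgeR adjusted p = 0.0232, 6 of 7), and thrb differed by −0.79 (edgeR adjusted p = 0.155). A cell that had turned fully mesenchymal would fall outside the epithelial clusters and so outside this comparison.

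Mesenchymal effectors and mmp11, which rose in epithelial cells at stage 61, could in principle be RNA from fibroblasts, free or in doublets. A single such source would give each gene about the ratio of epithelial to fibroblast-like CPM of the collagen genes col1a1, col1a2 and col3a1. The collagens' ratios were 0.000126 and 0.0012 in the stage 61 replicates. Of the 6 effectors that rose, 5 are described here. Among them itga5, cdh2 and itgb1 lay above the higher of these in both replicates beyond their 95% intervals (lowest ratio 0.0189), as did mmp11 (0.0788). Fibroblast RNA at the collagens' ratio is argued against for these 4 genes. The collagens were among the markers that named the fibroblast-like cluster, so epithelial clusters may lack cells rich in them. Fibroblast RNA at a higher ratio than theirs is therefore not excluded. The intervals cover counting error alone, and replicate 1 had 19 fibroblast-like cells, with 2 UMIs of cdh2. Macrophage-like cells of stage 61 also held mmp11, at the share given above, so for mmp11 free RNA from some source cannot be told apart. For fn1 and mmp2 fibroblast RNA cannot be told apart, since the lowest of their ratios, 0.000461 for fn1, lay between those of the collagens. The interval of mmp2 in replicate 1 reached down to 0.00127, and the fn1 call rested on stage 61 replicate 2 (log2 3.83 without it). Against the collagens of the same replicate both genes lay higher beyond the 95% intervals. Their lowest bounds were 0.000342 against 0.00016 in replicate 1 and 0.00195 against 0.00137 in replicate 2. Other cell types as a source were not tested. Expression in epithelial cells at climax remains an open biological explanation, found and tested on the same data.

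Ribosomal protein and oxidative phosphorylation genes were lower at stage 61, with a median log2 change of −1.81 over 149 members. The low depth of stage 61 replicate 2 is argued against as the whole cause, since the median was −1.40 without it, below the bound of −0.905 set at 50% of the change, although it was −2.51 without stage 61 replicate 1. The scaling factors cannot be told apart as a cause of the size of the fall, since the median was −0.89 without them, just short of that bound. For oxidative phosphorylation they are argued against as the whole cause. Without them 35 of 74 of its genes still fell and 0 rose, at a median of −1.18, while the median of all genes moved by 0.97. Among 75 ribosomal protein genes 3 then fell and 0 rose. Fewer enterocytes cannot be told apart either for the members as a whole, since within goblet-like cells the 4 pairs of replicates gave medians from −1.98 to −0.81. For oxidative phosphorylation alone that explanation stays open too, as those medians ran from −2.03 to −0.31 without the goblet-like cluster that expressed enterocyte genes, although the fitted median there was −1.20 (18 of 74 down), against −1.49 with that cluster (36 down) and −2.12 in all epithelial cells, and a change of growth and metabolism at climax is open and untested.

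In stage 61 replicate 2, the replicate of lowest total depth, 142 of 182 fibroblast-like cells (78%) held UMIs of general epithelial markers after thinning to 1000 UMIs. Free epithelial RNA is argued against only for the markers over 2 times as high in fibroblast-like as in macrophage-like cells. Summed over markers, the CPM in fibroblast-like cells was 3.09 times that in macrophage-like cells. The 95% interval of this ratio, 2.61 to 3.60, does not cover variation between replicates. Per cell the sums were 20.2 against 4.54 UMIs at median depths of 4076.5 and 2236.5. Keratins weighed most, with 835, 776 and 693 fibroblast-like UMIs of krt19, krt8.1 and krt18.1. Any other of the 16 markers below had at most 295. Whether fibroblast-like cells express these keratins themselves was not tested. Single markers had no interval. Of 16 markers with at least 20 UMIs, 12 were over 2 times as high, krt19 most (768 against 17.2 CPM), 3 were less than that, among them cdh1 (231 against 155 CPM) and elf3 (73.6 against 40.8 CPM), and cdh17 was lower (239 against 456 CPM). For the markers not over 2 times as high, free RNA is not argued against. Doublets of a fibroblast and an epithelial cell cannot be told apart as a source. The median doublet score of the 142 cells with such UMIs was 0.0755 (0.0724 to 0.0788), an interval that spans the replicate's 75th percentile of 0.0779. Fibroblast-like cells without such UMIs had a median score of 0.0783, so the score did not follow the markers. Their median depth was 3905.5 UMIs against 5290.5 with such UMIs, and the highest-scoring barcodes had been removed before. Cells between an epithelial and a mesenchymal state, which the series title brings to mind, may also give such profiles, and no test here separates them from doublets.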
